A study of Leucoraja erinaceus with 4 samples.

How the data were processed

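Messenger RNA was measured by RNA sequencing in 4 samples from 1 adult little skate, a cartilaginous fish that senses weak electric fields with ampullary organs. The samples were ampullary receptor cells (the electroreceptor cells), ampullary canals (the tubes that lead to them), body skin without electroreceptors, and liver. Each tissue gave 1 library. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with Trizol, and 1 µg of total RNA went into a stranded, poly(A)-selected Illumina library. The liver sample weighed 4 mg per the labels.

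Reads were assigned to an assembled transcriptome and summed per assembled gene with RSEM 1.1.17, per the submitters' processing notes. The assembler, the read aligner, the filters and the libraries used for the assembly are not given in the sources used here. The deposited files list the same 186064 assembled genes, made of 221472 transcripts, in every library, and 19914 assembled genes have 2 or more transcripts (at most 20). Of the 186064 assembled genes, 36188 had no read in any of the 4 libraries. The median assembled gene is 309 bases long and the shortest 201 bases. Per the file headers, the authors' expected counts are estimated reads per assembled gene and are not normalized. Between 200 and 287 of these values per library differed from a whole number by more than 0.001. The deposited TPM values are transcript shares scaled by RSEM to the same total in each library, per the file headers, and summed to 999993.1 to 1000004. The deposited FPKM values, scaled for length and depth per the file headers, are proportional to TPM within a library and were not used further. The length columns hold each assembled gene's mean length over its transcripts, weighted by their abundance in that library. The difference between length and effective length corresponds to mean fragment lengths of 219.86 bases in receptor cells, 209.74 in canals, 229.55 in skin and 224.11 in liver.

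The identifiers are assembly numbers. The files do not pair them with gene names, and 0 identifiers matched the 23250 genes of the reference gene table (assembly Leri_hhj_1). Gene names, gene functions and genome positions were therefore not analysed here. The lists of ion channel, synapse, hair cell, mucin, calcium-handling, energy and osmolyte genes and of cell type markers that were fixed before the data were examined have no measured member, and no list statistic was computed. An assembled gene can be a fragment, an allele or a close copy of another, and RSEM divides reads among such sequences, so counts of assembled genes are not counts of genes. Identifiers that share the part before "_g" belong to 1 assembly cluster, and there were 172360 clusters.

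Expected counts were rounded to whole numbers. Assembled genes with at least 10 reads in at least 1 library were kept (36326, which held at least 98.75% of the reads of every library). Library sizes were scaled with TMM factors over the 4 libraries (edgeR 4.0.16, R 4.3.3), which were 1.476 for receptor cells, 1.01 for canals, 1.111 for skin and 0.6041 for liver. Values are counts per 1000000 reads of the scaled library size (CPM), and differences are on the log2(CPM + 0.5) scale, which understates the change of low values. With 1 library per tissue and 1 animal there is no replicate check of any difference, and no p-value was computed. Assembled genes were counted when 2 libraries differed by at least 4-fold, a rule of size. Ratios of single assembled genes carry an exact 95% interval (Clopper-Pearson on the 2 counts), and 0 reads were treated as allowing up to 3. An "at least" fold rests on these 3 reads, close to a 1-sided limit, and is therefore larger than the lower end of the 2-sided interval would be. These intervals and limits cover the counting error of independent reads only. Reads from PCR copies are not independent molecules, so the intervals can be too narrow even for that. With 1 library per tissue, differences between animals, dissections and library preparations are not covered. The intervals and limits also leave out the choice of scaling. With library totals, folds of receptor cells over canals, skin and liver are 1.46, 1.33 and 2.44 times as large. Folds the other way are smaller by the same factors. Reads misplaced between libraries are left out too, and matter most where the lower library has few reads. Totals of 11071249 to 12303108 reads make the exact binomial 95% interval of any share of a library's reads at most 0.059 percentage points wide. The limit of 3 reads equals 0.166 CPM in receptor cells, 0.241 in canals, 0.231 in skin and 0.449 in liver.

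The rule fixed before the data were examined allowed at most 2 identifiers per direction and comparison when no gene names exist. They are the 2 assembled genes, among those with at least 100 reads in 1 of both libraries, whose ratio interval ends farthest from no difference. The comparisons were receptor cells against canals, skin and liver, and canals against skin, plus the assembled genes of each tissue that were at least 4-fold above every other tissue. To show what counting noise alone gives, 20 sets of 4 libraries with common proportions and Poisson counts were simulated. None of the 12 counts of assembled genes exceeded 0 in any of them. These simulated libraries were scaled by their totals. The pseudocount shrinks differences of low values, so this result says little of assembled genes with few reads. Because 3 comparisons share the receptor-cell library, the overlap of their lists was also computed after each library's deviations from the mean over libraries were reshuffled on their own among assembled genes of similar mean expression (100 reshufflings). The counting was also tested on simulated data with 200 assembled genes changed 8-fold among 29610. In receptor cells against canals, 100 of 100 increases and 99 of 100 decreases passed the 4-fold rule, as did 100 of 100 in each direction against skin and against liver, and 0 unchanged assembled genes passed. The changed ones were drawn from those expected to have 100 reads or more in every library before the change. All other proportions were common to the libraries. The test therefore does not cover low counts or the scaling of libraries of unlike composition. Alternatives were library totals, DESeq2 1.42.0 size factors, the deposited TPM, pseudocounts of 0.1 and 2, minimums of 1 and 100 reads, library sizes without the 50 most dominant assembled genes, and a 4-fold rule on the interval end. Added after seeing the data were sums per assembly cluster, a minimum length of 300 bases, and TMM factors without liver. Numbers were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.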

Results

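The transcriptome of the ampullary receptor cells of 1 adult skate was compared with that of 3 other tissues of the same animal. Similar numbers of reads were assigned to assembled genes in the libraries of ampullary receptor cells (12240037 reads), ampullary canals (12303108), body skin (11716890) and liver (11071249). The receptor-cell library spread its reads over the most assembled genes. At least 1 read fell on 98988 assembled genes in receptor cells, 65961 in canals, 68576 in skin and 67936 in liver. At least 100 reads fell on 12302, 10098, 10376 and 7357 assembled genes, respectively. Liver had the most concentrated transcriptome, with 48.2% of its reads on its 50 most abundant assembled genes, against 18.9% in receptor cells, 27.9% in canals and 23.8% in skin. The single most abundant assembled gene took 4.17% of the reads in receptor cells (exact binomial 95% interval 4.15 to 4.18), 3.16% in canals (3.15 to 3.17), 2.12% in skin (2.11 to 2.13) and 3.97% in liver (3.96 to 3.98).

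**Figure D1:**
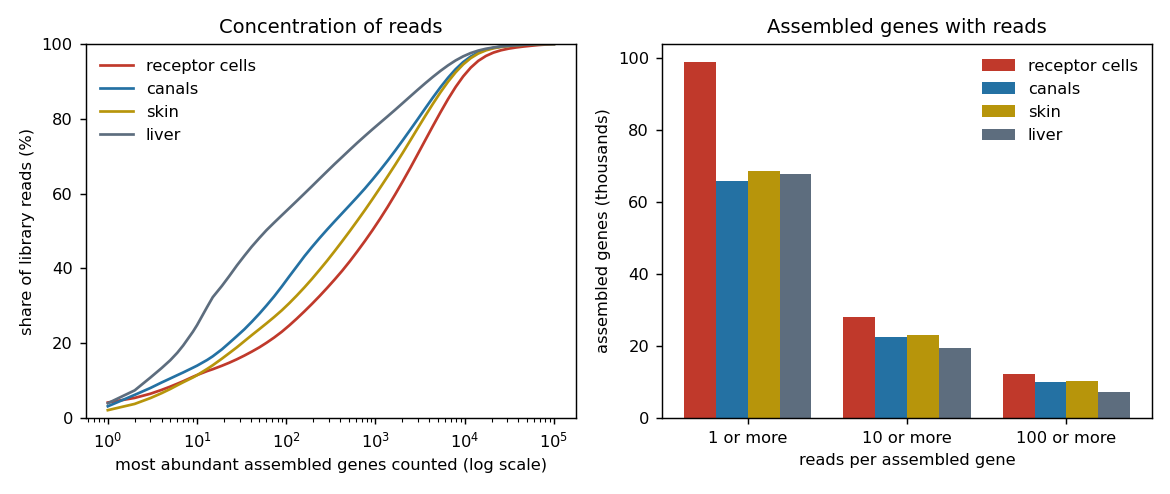
Left, the cumulative share of each library's reads (%, y axis) on its most abundant assembled genes, ranked from the top (x axis, log scale). Right, the number of assembled genes (y axis, in units of 1000) with at least 1, 10 or 100 reads in each library. Each line or bar is 1 library. The liver curve rises fastest, reaching 77.9% at 1000 assembled genes against 51.4% in receptor cells, and receptor cells have the tallest bar in each class.

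A set of 14283 assembled genes had at least 10 reads in every library and held 85.2% of the reads in receptor cells, 92.6% in canals, 86.5% in skin and 81.1% in liver. Of these, 3826 (26.8%) stayed within 2-fold across all 4 tissues. Receptor cells were most similar to canals, with Spearman's rho = 0.727 and Pearson's r = 0.795 of log2 CPM across 36326 assembled genes. Similarity to skin (rho = 0.677, r = 0.739) and to liver (rho = 0.599, r = 0.655) was lower. Canals and skin had rho = 0.687, canals and liver 0.625, and skin and liver 0.658. These 6 coefficients are across assembled genes, which are not independent replicates. Of the 100 most abundant assembled genes of receptor cells, 48 were also among the 100 most abundant of canals, 34 of skin and 15 of liver. A core of 15 was shared by the top 100 of all 4 libraries and took between 6.78% and 11.2% of the reads of each.

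The comparison of receptor cells with canals asked which transcripts set the receptor-cell sample apart from the tube of the same organ. Without gene names, the cell types in that sample could not be checked, so differences belong to the sample as dissected. In receptor cells, 3100 assembled genes were at least 4-fold higher than in canals and 2364 at least 4-fold lower, out of 36326. The 3100 higher ones took 18.9% of the receptor-cell reads and 0.804% of the canal reads. The 2364 lower ones took 38.3% of the canal reads and still 7.29% of the receptor-cell reads. At least 16-fold differences were found for 589 higher and 276 lower assembled genes. Among the higher group, 928 had no read in canals, and 248 of these had 100 reads or more in receptor cells. Assembled gene c131483_g1 (729 bases) had 107200 reads in receptor cells (5935 CPM) and 27 in canals, a 2731-fold difference (95% interval 1877 to 4145), with 7 reads in skin and 10 in liver. Assembled gene c87266_g3 (2982 bases) had 8373 reads in receptor cells and 0 in canals, at least 1920-fold higher, with 1 read each in skin and liver. In the other direction, c68108_g2 (386 bases) had 11311 reads in canals and 27 in receptor cells, 609-fold higher in canals (418.3 to 924.5). Assembled gene c82302_g1 had 682 reads in canals and 0 in the other 3 libraries, at least 330.5-fold higher in canals than in receptor cells. The split of 56.7% higher to 43.3% lower depended on the scaling and became 74.7% to 25.3% with library totals and 77.6% to 22.4% with the deposited TPM. The median difference over all assembled genes moved from 0.11 to 0.50 and 0.66 on the log2 scale, respectively, so a direction is relative to the scaling chosen. The counts also depended on the pseudocount, with 7032 higher and 4107 lower at 0.1, and 1348 and 1189 at 2.

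The comparison of receptor cells with body skin set the electroreceptor tissue against skin that lacks it. Receptor cells had 3227 assembled genes at least 4-fold higher and 3005 at least 4-fold lower. The higher group took 22.2% of the receptor-cell reads and 0.967% of the skin reads, and the lower group took 38.3% of the skin reads and 3.65% of the receptor-cell reads. Differences of at least 16-fold were found for 770 higher and 684 lower assembled genes. No skin read was found for 986 of the higher group, including 341 with 100 reads or more in receptor cells. Assembled gene c131483_g1 was 11030-fold higher in receptor cells (5355 to 27440). Assembled gene c86908_g1 (1600 bases) had 23807 reads in receptor cells, 4720 in canals, 0 in skin and 1 in liver, at least 5717-fold higher in receptor cells than in skin. The other direction was led by c65320_g1 (3429 bases), with 63485 reads in skin and 3 in receptor cells, 29370-fold higher in skin (10050 to 142400). Assembled gene c93571_g1 (1671 bases) had 56729 reads in skin and 4 in receptor cells, 19680-fold higher in skin (7688 to 72250). The share of higher among these, 51.8%, became 63.9% with library totals, 67.4% with the deposited TPM and 48.9% with DESeq2 size factors. The median difference moved from 0.15 to 0.44, 0.53 and 0.08, in that order. A pseudocount of 0.1 gave 6845 higher and 4609 lower, and a pseudocount of 2 gave 1537 and 1723.

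Of the 3 tissues compared with receptor cells, liver differed by the largest number of assembled genes. In receptor cells, 3907 assembled genes were at least 4-fold higher than in liver and 3726 at least 4-fold lower, and 992 and 1013 of them differed by at least 16-fold. The higher group took 24.8% of the receptor-cell reads and 0.548% of the liver reads. The lower group took 65.1% of the liver reads and 3.0% of the receptor-cell reads. No liver read was found for 1516 of the higher group, and 552 of these had 100 reads or more in receptor cells. Assembled gene c76333_g1 (1638 bases) had 124629 reads in receptor cells and 12 in liver, 3846-fold higher (2201 to 7443), with 3487 reads in canals and 12 in skin. Assembled gene c131483_g1 was 3969-fold higher in receptor cells than in liver (2158 to 8278). Assembled gene c89492_g1 (14271 bases) had 378683 reads in liver and 29 in receptor cells, 35270-fold higher in liver (24550 to 52660). Assembled gene c70616_g2 (2076 bases) had 218921 reads in liver and 15 in receptor cells, 39420-fold higher in liver (23900 to 70420). The share of higher among these, 51.2%, became 80.0% with library totals, 79.0% with the deposited TPM and 48.2% with DESeq2 size factors. The median difference moved from 0.15 to 1.07, 1.18 and 0.12, in that order. With library totals the folds of c76333_g1 and c131483_g1 became 9394 and 9696, and those of c89492_g1 and c70616_g2 became 14440 and 16140, so the printed intervals hold for the main scaling only. A pseudocount of 0.1 gave 7554 higher and 4924 lower, and a pseudocount of 2 gave 1903 and 1972.

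**Figure D2:**
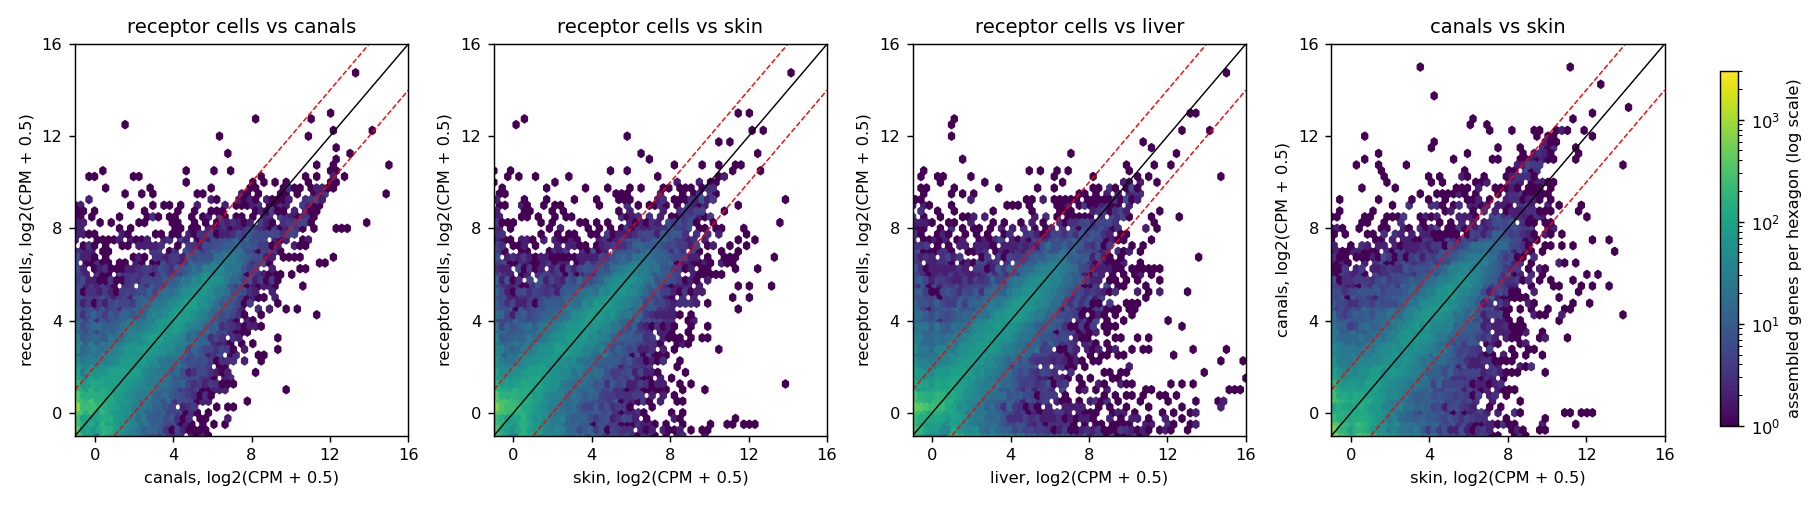
Expression of 36326 assembled genes in 4 pairs of libraries, as log2(CPM + 0.5) on both axes, with color giving the number of assembled genes per hexagon on a log scale. The black line marks equal expression and the dashed red lines 4-fold differences. In the panel of receptor cells against canals, 3100 assembled genes lie on or above the upper dashed line and 2364 on or below the lower one.

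Canals and skin were compared with each other to give the difference between tissues when neither is the receptor-cell sample. In canals, 3354 assembled genes were at least 4-fold higher than in skin and 3491 at least 4-fold lower, and 723 and 869 of them differed by at least 16-fold. The counts were 3226 and 3902 with library totals and 4113 and 5769 with the deposited TPM. A pseudocount of 0.1 gave 5711 and 6207, and a pseudocount of 2 gave 1700 and 1865. The group higher in canals took 32.9% of the canal reads and 2.49% of the skin reads. The group higher in skin took 36.0% of the skin reads and 1.92% of the canal reads. Assembled gene c51194_g1 (1257 bases) had 55627 reads in canals and 14 in skin, 4162-fold higher (2480 to 7613). Assembled gene c80805_g1, the most abundant of the canal library with 388787 reads, had 158 in skin, 2577-fold higher in canals (2205 to 3032). Both were also present in receptor cells, with 1939 and 14193 reads. Assembled genes c65320_g1 and c93571_g1, which led the skin side against receptor cells, led it here too, at 8659-fold (4202 to 21540) and 7738-fold (3755 to 19250) higher in skin than in canals.

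Each tissue had a set of assembled genes at least 4-fold above every other tissue. The receptor-cell set held 1446 assembled genes and 13.2% of the reads of that library, against at most 0.362% of the reads of any other. The canal set held 1333 and 20.6% of the canal reads, but up to 2.2% of the reads of another library. The skin set held 1580 and 27.6% of the skin reads, and the liver set 2357 and 58.2% of the liver reads. Of the receptor-cell set, 950 had 100 reads or more, 253 had 1000 or more, 346 stood at least 16-fold above every other tissue, and 356 had no read elsewhere. The corresponding number without a read elsewhere was 162 for canals, 249 for skin and 790 for liver. The scaling makes the 4-fold rule ask for more reads in receptor cells than in liver, so these numbers are not counted alike. With a minimum of 10 reads in its own library and none elsewhere, receptor cells had 1180, canals 412, skin 488 and liver 859. The order of the sets depended on the settings: the receptor-cell and liver sets held 2382 and 1449 with library totals, 3650 and 1999 with the deposited TPM, and 2927 and 2869 with a pseudocount of 0.1. Assembled genes higher in receptor cells than in canals overlapped those higher than in skin in 1767 cases (independent lists 275.4) and those higher than in liver in 1949 (333.4). Those higher than in skin and than in liver overlapped in 2227 cases (347.1). These overlaps were 57.0%, 62.9% and 69.0% of the smaller list. Lists that share the receptor-cell library overlap without any link between the other tissues. When each library's deviations were reshuffled on their own among assembled genes of similar mean expression, the overlaps were on average 1965, 1959 and 1915. In counts, only the overlap of the skin and liver lists was above its reshuffled value. The reshuffled lists were longer, with 4086 against canals, 3987 against skin and 4280 against liver, where 3100, 3227 and 3907 were observed. As shares of the smaller list, the reshuffled overlaps were 49.3%, 47.9% and 48.0%. Much of the excess over independent lists may therefore come from the shared library, which cannot be split.

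A further count, added after the data were seen, took assembled genes that were at least 4-fold higher in both tissues of a pair than in either of the remaining tissues. Receptor cells and canals shared the most, 514, which took 5.52% of the receptor-cell reads and 10.8% of the canal reads. Receptor cells and skin shared 293, and skin and liver 241. The other pairs shared 123 (receptor cells and liver), 115 (canals and skin) and 111 (canals and liver). With library totals the numbers were 805, 494 and 127 for the first 3 pairs, in that order, and 113, 87 and 53 for the others. With DESeq2 size factors they were 482, 276, 257, 122, 122 and 124.

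**Figure D3:**
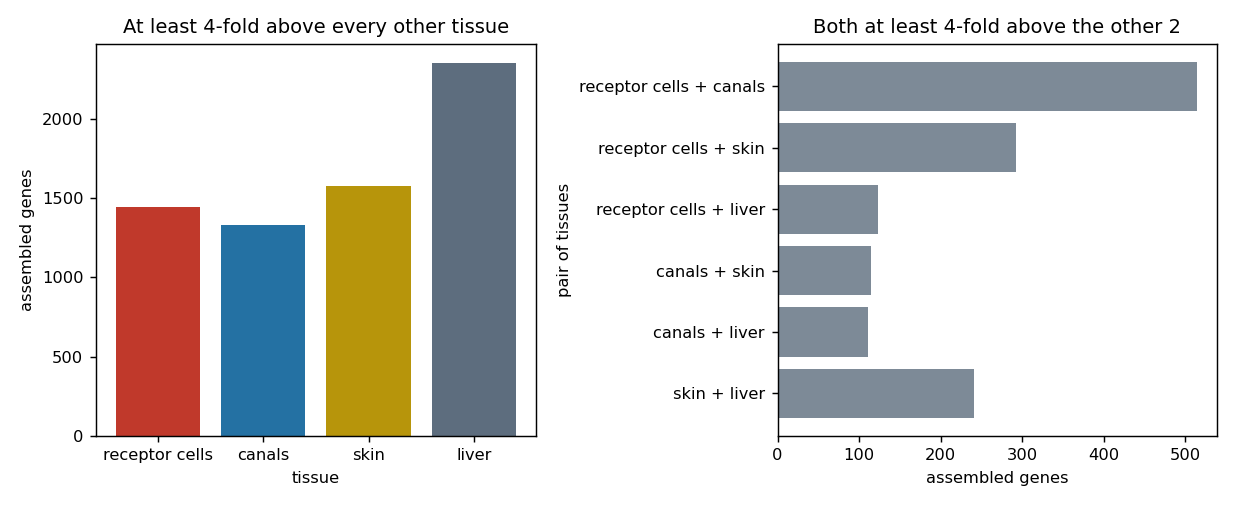
Left, the number of assembled genes (y axis) at least 4-fold above every other tissue in each of the 4 tissues. Right, the number (x axis) at least 4-fold higher in both tissues of a pair than in the remaining tissues. Bars are counts from 1 library per tissue and carry no error. With the main settings shown, the liver bar is 2357 and the receptor-cell bar 1446, an order that turns with library totals (1449 and 2382), and the bar of receptor cells with canals is 514.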

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

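No paired analysis was possible because each tissue has 1 library, and no library could be left out of a group for the same reason. Of the 138 values that the 12 counts of assembled genes took under the alternatives, 98 lay within 1.5 times the reported count and 40 did not. DESeq2 size factors, a minimum of 1 read, library sizes without the 50 most dominant assembled genes, the 4-fold rule on the interval end, and the choices made after seeing the data (cluster sums, a minimum length, TMM factors without liver) moved none of the 12 counts by more than 1.5 times where they were run. With library totals, the counts higher in receptor cells were 4923 against canals and 8041 against liver, 2010 were lower than in liver, and the sets of their own were 2382 for receptor cells and 1449 for liver. Leaving 50 dominant assembled genes out of these totals (13% of the receptor-cell reads and 42.3% of the liver reads) changed the share higher than in liver among the differing ones from 80.0% to 67.9%, and restricting the count with full totals to those with 100 reads or more in receptor cells or liver changed it to 81.8%. With the deposited TPM, 7926, 6987 and 10595 were higher in receptor cells than in canals, skin and liver, 5769 were lower in canals than in skin, and the receptor-cell set was 3650. With a pseudocount of 0.1, receptor cells had 7032 higher and 4107 lower against canals, 6845 and 4609 against skin, and 7554 higher against liver, canals had 5711 higher and 6207 lower against skin, and the sets were 2927 for receptor cells and 2208 for canals. With a pseudocount of 2, the higher and lower counts were 1348 and 1189 against canals, 1537 and 1723 against skin, 1903 and 1972 against liver, and 1700 and 1865 for canals against skin, and the sets were 737 for receptor cells, 665 for canals, 967 for skin and 1276 for liver. A larger pseudocount shrinks differences of low values by construction. With a minimum of 100 reads, which tests fewer assembled genes, receptor cells had 2037 higher and 1390 lower against canals, 1926 lower against skin and 1880 lower against liver, canals had 2040 higher and 2215 lower against skin, and the sets were 750 for canals, 1041 for skin and 1081 for liver. The cause of the other movements was not tested. The log2 differences of the named assembled genes, 16 values under 8 alternatives, kept their direction in all 128 cases, which says little of genes chosen for large differences. Their sizes did not hold: 37 moved by more than 1.5-fold, 15 of them with a pseudocount of 2, 10 with the deposited TPM, 8 with a pseudocount of 0.1 and 4 with library totals. By the counting interval 54 counted as moved, 34 of them from 5 values that lay outside their interval before any change. Sums per gene name and the statistics of the fixed gene lists were not run, since the files pair no names with the identifiers. At this depth, 0 reads allow up to 0.449 CPM in liver and 0.166 in receptor cells, a gap that comes from the scaling, since with library totals the limits are 0.271 and 0.245.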

Other observations

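The patterns below were noticed in the data. The tests of a fixed share of canal tissue, of misplaced reads, of an assembly from 1 library, and of dominance against canals and skin, and the counts on lengths and clusters, were chosen after related values were seen. The isoform-weighted lengths describe which transcripts of an assembled gene were used. Among 4565 assembled genes with 2 or more transcripts and at least 100 reads in both receptor cells and canals, 71 were at least 1.5-fold longer in receptor cells and 72 at least 1.5-fold longer in canals. The same comparison gave 41 and 50 of 4362 for receptor cells and skin, and 53 and 42 of 3154 for receptor cells and liver. The median absolute log2 difference was 0.032 between receptor cells and canals (95% resampling interval 0.030 to 0.035) and 0.020 between receptor cells and skin (0.018 to 0.022). It was also 0.029 between canals and skin and 0.030 between canals and liver, against 0.020 between receptor cells and liver and 0.018 between skin and liver, at this minimum of 100 reads. With at least 1000 reads in both libraries, 3 and 3 of 498 were at least 1.5-fold longer in receptor cells or canals, and the median was 0.019 (0.015 to 0.024) for that pair against 0.014 (0.009 to 0.019) for receptor cells and skin, so the intervals overlapped. Isoform counts were not used here, so these lengths carry no error of their own.

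The receptor-cell set had a median length of 1294 bases. The median of 10000 random lists of the same size matched on mean expression was 864 bases (central 95% from 831.5 to 900.0), and the set lay at percentile 100. The skin set had a median of 1270 bases against 1017 (977.3 to 1057) and the canal set 1037 against 983.4 (944.0 to 1026). The liver set had a median of 876 bases against 902 (874 to 928), within the random lists. These lists were matched on the mean over the 4 libraries, not on the reads in the set's own library. The median number of reads there was 178.5 in receptor cells, 224.5 in skin, 152 in canals and 72 in liver. The lists therefore cannot separate length from number of reads, and no conclusion is drawn from them. Assembled genes of 1 assembly cluster that both differed at least 4-fold between receptor cells and canals went the same way in 330 of 448 pairs (73.7%), against 50.8% on average and 59.2% at most in 1000 reshufflings, and 86 clusters held members in both directions. Each of the 65 assembled genes with 50000 reads or more in any library had reads in all 4 libraries. The lowest values per 1000000 liver reads were 39.0 in receptor cells, 39.9 in canals and 40.8 in skin. The few reads behind some of the largest folds lie near these values, such as 47.3 receptor-cell reads per 1000000 skin reads for c65320_g1. Whether so few reads come from the tissue or were misplaced from another library was not tested, and the size of these folds depends on it.

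A group of 80 abundant assembled genes shorter than 1000 bases (mean log2 CPM of at least 8) lay together below its canal level in receptor cells, with a median log2 difference of -2.03 and quartiles of -2.27 and -1.58. The 187 equally abundant ones of 1000 bases or more also lay below canals, less far and more widely spread (median -0.855, quartiles -1.59 and -0.088, 44 of them higher in receptor cells). In 72 of the 80 the canal value was also above skin (median 1.59), whereas receptor cells and skin differed by a median of -0.41. With library totals the median was still -1.48 (95% resampling interval -1.63 to -1.37, which covers the spread among these assembled genes only). That change of scaling moves all abundant assembled genes alike, by an amount set by the library factors, so it does not test scaling in general. A scale factor also leaves the gap between the shorter and the longer ones (-2.03 against -0.855), so scaling alone cannot give that gap. Whether a length bias from the shorter fragments of the canal library contributes was not decided. The 420 less abundant assembled genes of that length (mean log2 CPM of 4 to 8) had a median of -0.722 (-0.802 to -0.618), between the values that would speak for and against it. The median of 5883 longer ones was -0.17. Fragments were also shorter in receptor cells than in skin and liver. There the abundant short and long ones had medians of -0.412 and -0.491 (minus skin) and -0.678 and -0.435 (minus liver), so the short ones were not clearly raised. Skin had longer fragments than liver, and its short ones lay lower (-0.261 against -0.038), the direction of such a bias. The pairs without canals thus go both ways. A shared difference in the activity of 1 gene group between the tissues stays open and was not tested.

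Assembled genes abundant in canals were also found in receptor cells. For the 23 with 50000 canal reads or more, the lowest ratio was 32600 receptor-cell reads per 1000000 canal reads, while in skin it was 252 and in liver 108. Canal tissue mixed in at 1 fixed share is argued against as the whole cause: of all 1735 assembled genes with 1000 canal reads or more, 14 had a ratio whose interval (Bonferroni, 95% over all of them) ended below 3.26%. The lowest ratio was 0.239% with an upper end of 0.494%. It rests on 1 assembled gene, c68108_g2 (386 bases, 27 receptor-cell reads against 11311 canal reads), and its interval covers counting error only. Reads divided among close copies or a length bias could lower it, so 0.494% is not a firm limit on such a share. With the same reservation, misplaced reads at 1 fixed rate are argued against as the whole cause. The value of 0.494% lies below 3.18%, the lower end of the interval of the lowest ratio among the 23. Canal tissue of uneven composition, and expression of these transcripts by the receptor-cell tissue itself, stay open and were not tested.

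More assembled genes had reads in receptor cells than in the other libraries. Much of this lay at few reads. Reads in receptor cells only were found for 32199 assembled genes, of which 1180 had 10 or more. The corresponding numbers were 14094 and 412 in canals, 12228 and 488 in skin, and 15118 and 859 in liver. Depth, in reads assigned to assembled genes, is argued against, because after thinning to 11071249 reads each the number was still 1.41 times that of the next library. An assembly from the receptor-cell library alone is argued against by 2756 assembled genes with 10 reads or more in another library and none in receptor cells. This count cannot tell whether the assembly drew more on that library than on the others, which was not tested. When the 1000 most abundant assembled genes of every library were removed and 2033097 reads drawn from each, the ratio was 1.32 to skin, which argues against dominance by a few transcripts there and in canals, but 1.07 to liver, where dominance cannot be told apart from a wider range of transcripts. A mixture of more cell types in the receptor-cell sample may also contribute and was not tested.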
